A study of Homo sapiens with 9 samples.

How the data were processed

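RNA was profiled in HepG2, an established line of human liver tumour cells, in 3 groups of 3 libraries. The groups were control cells, cells given oleic acid (a monounsaturated fatty acid), and cells given oleic acid and then sesamin (a lignan of sesame seed). Per the labels, oleic acid was added 24 h after the cells had attached and left on for 24 h at a concentration of 400, and sesamin was then given at 16 for 36 h more. The metric prefix before the M of both concentrations is lost in the labels, so neither is given here as a molarity. The labels do not state a vehicle, whether the groups were harvested at the same total time in culture, or whether the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

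The deposited count table held whole read counts for 60605 Ensembl genes, 1 column per library, and 27767 of the genes had at least 1 read. The libraries were made with a stranded kit that selects poly(A) RNA, per the labels. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Cufflinks and HTSeq, and the genome build was hg38. The role and version of each tool, the annotation release and the strand setting of the counting were not given in the sources used here, so antisense and overlapping genes are uncertain. The FPKM table that the authors deposited held the 27767 genes with a read. In all 23697 genes where this could be compared, the count divided by the FPKM gave 1 gene length times the library total within a relative tolerance of 1e-05. No column of values per library was left unused.

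Total counts per library lay between 15501727 and 17298770. Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 14054 genes, 11957 of them protein coding, with at least 99.88% of the counts of every library. Counts were scaled with TMM factors, and a negative binomial model with a mean per group was fitted to all 9 libraries, which left 6 residual degrees of freedom and a common biological coefficient of variation of 0.0888. Differences were tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest, two-sided) with Benjamini-Hochberg adjustment over all tested genes, and a gene is said to have risen, fallen or changed at an adjusted p under 0.05. Levels are TMM-normalised CPM as mean ± SD of 3 libraries, and log2 fold changes are given ± SE.

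The 36 gene lists held fatty acid oxidation, PPAR targets, fatty acid synthesis and desaturation, cholesterol synthesis and uptake, triglyceride synthesis, lipid droplet and lipolysis, fatty acid uptake and activation, and lipoprotein secretion. They also held liver X receptor targets, bile acid synthesis and transport, glucose production and insulin response, aryl hydrocarbon receptor targets, PXR and CAR targets, and NRF2 targets. Lists of stress and growth were unfolded protein response, integrated stress response, acute phase and complement, NF-kB and cytokine response, interferon response, mitotic cell cycle, DNA replication, p53 targets, hypoxia and glycolysis, hepatocyte identity, autophagy and lysosome, metallothioneins, immediate early genes, and heat shock response. The others were nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, and markers of fibroblasts and stellate cells, endothelial cells, immune cells, and cholangiocytes and progenitors. The 34 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1, two-sided, correlation between genes preset at 0.01), with adjustment over the lists. The same test with a correlation estimated per list, and fry, a rotation test of a list on its own, were alternatives. Annotation terms deposited with the counts (10 to 500 tested genes, 2855 terms) were tested with Fisher's exact test, one-sided, with the tested genes that carry any term of the same kind as background and adjustment per comparison and direction.

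Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, up to 4 members of lowest p per list, a fixed panel of 16 genes, and the 6 genes that moved most in each way among those called with both oleic acid and sesamin. Values are given for a part of the genes the rule took, and some genes are not reported here. Genes named beside a count of 5 or fewer without a value were chosen after their values were seen. Reads of near-identical copies may have been divided between genes, so ACOT1, ACOT2, MT1G, GSTA2 and ribosomal proteins with pseudogenes are uncertain.

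The alternatives were RLE factors, DESeq2 1.42.0, no or a stricter count filter (CPM of at least 1 in at least 3 libraries), only the 6 libraries compared, the replicate number as a block, each library left out in turn, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 0.1, limma on log2(FPKM + 1) without that filter, and fold thresholds (2-fold, or glmTreat against 1.5-fold). Fold changes on the log2(FPKM + pseudocount) scale understate the change of low genes. Alternatives added after the data had been seen were library totals without TMM factors, RLE factors for the lists, recomputed annotation terms, and offsets that removed each library's smooth trend on GC content and gene length. GC content came from the longest transcript of each gene in GENCODE release 29, matched by Ensembl identifier for 13965 of the 14054 genes, and gene length from the deposited tables. The oleic acid libraries enter both the oleic acid and the sesamin comparison, and 50 simulated data sets gave the overlap that independent noise in those shared libraries produces on its own.

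Each step was tested on simulated data drawn from the real means and library sizes with 200 genes changed. For oleic acid against control (13838 genes), edgeR recovered 64.2% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 92.4% of those changed 4-fold, and 8.77% of the calls were of genes that had not been changed. For sesamin against oleic acid (13857 genes) the shares were 68.7%, 68.7% and 98.5%, with 7.1% of the calls false. For sesamin against control (13832 genes) they were 62.7%, 79.1% and 93.9%, with 10.3% of the calls false. These data were drawn with independent genes and no trend on GC content, so the shares need not hold for the real calls. With only a GC trend of a chosen size put on 1 group, 3791, 3693 and 3724 genes were called in the same order of comparisons. Once trends on GC content and length were removed, 3, 0 and 1 were. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).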

Results

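HepG2 cells were sequenced as control, after oleic acid, and after oleic acid followed by sesamin, to ask whether sesamin alters the lipid load that oleic acid is given to bring. Each group had 3 libraries, with total counts from 15501727 to 17298770 and 19575 to 20301 genes with at least 1 read. Libraries of 1 group differed by more than counting error, with a chi-square per degree of freedom of 3.44 to 7.90 between control libraries, 3.85 to 4.97 between oleic acid libraries and 11.4 to 21.8 between sesamin libraries, so no pair was treated as repeats of a single library. Mitochondrially encoded genes took 7.80 to 8.41% of the counts in control, 10.1 to 10.5% with oleic acid and 9.82 to 11.9% with sesamin. The first principal component held 40.4% of the variance and put control at -38.0 to -27.3, oleic acid at 4.46 to 12.3 and sesamin at 18.3 to 33.4. The next held 16.3% and put oleic acid at -24.1 to -18.5, below control (2.66 to 11.8) and sesamin (0.356 to 23.8). Genes also moved with their GC content. The fifth of genes with the lowest GC content (27.8 to 41.1%) had a median deviation from the mean of all libraries (log2 CPM) of 0.03 to 0.22 in control, 0.01 to 0.08 with oleic acid and -0.33 to -0.04 with sesamin. In the fifth with the highest GC content (58.4 to 75.8%) these medians were -0.21 to -0.04, -0.03 to 0.03 and 0.15 to 0.17.

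**Figure D1:**
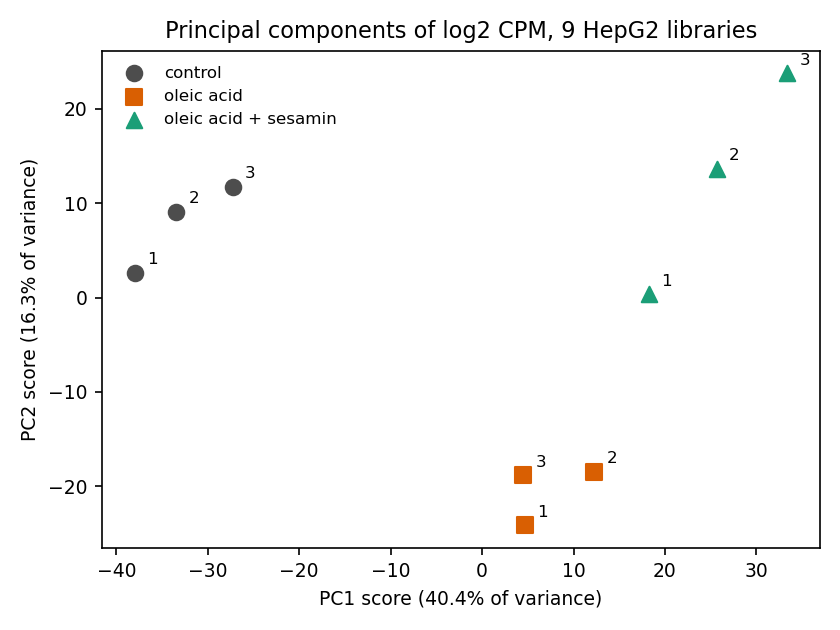
Scores of the 9 libraries on the first (x axis, 40.4% of the variance) and next (y axis, 16.3%) principal components of log2 CPM, 1 point per library, coloured by group. Control lies below -27 on the x axis, and oleic acid lies below -18 on the y axis, apart from both other groups.

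**Figure D2:**
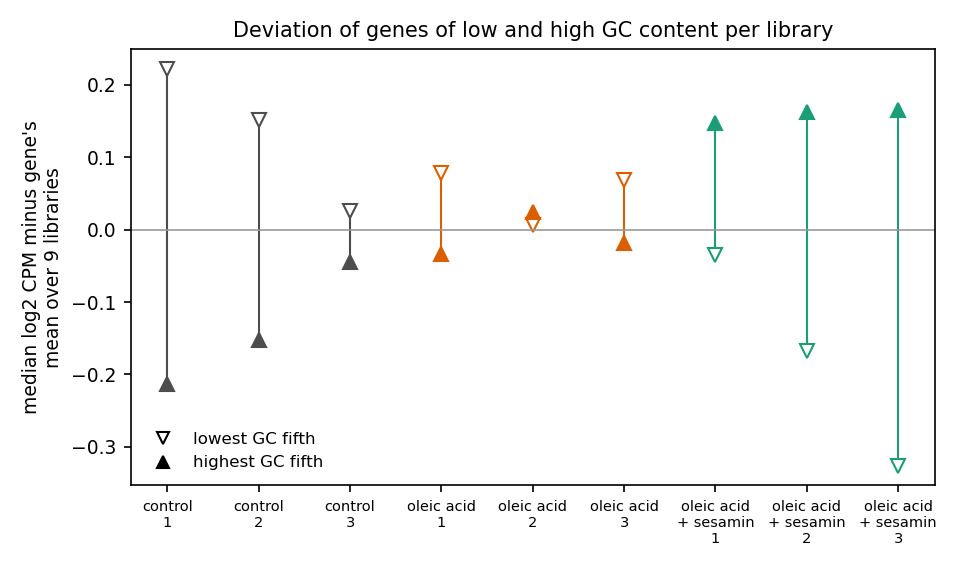
Median deviation of each library from the mean of all 9 libraries (log2 CPM, y axis) for the fifth of genes with the lowest and the fifth with the highest GC content, 1 point per library, by group (x axis). With sesamin the low-GC genes lie at -0.33 to -0.04 and the high-GC genes at 0.15 to 0.17.

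The comparison of oleic acid with control asks how the libraries labelled oleic acid differed from those labelled control. Genes of glycolysis and of the response to low oxygen were lower with oleic acid. PFKFB4, a regulator of glycolytic flux, had 194 ± 5.41 normalised CPM in control and 55.2 ± 2.10 with oleic acid (SD, n = 3), and it fell by 1.81 ± 0.07 on the log2 scale. BNIP3, a mitophagy receptor induced by hypoxia, went from 983 ± 32.3 to 343 ± 24.4 CPM, a log2 fold change of -1.52 ± 0.07 (SE). NDRG1, a stress-responsive gene, went from 792 ± 45.7 to 302 ± 28.5 CPM, and EGLN3, a prolyl hydroxylase that acts on hypoxia-inducible factor, from 61.0 ± 1.75 to 19.2 ± 1.36 CPM. Of the 32 measured members of the hypoxia and glycolysis list, 31 fell and 1 (PFKP) rose, with the counts adjusted over the list alone the same at 31 and 1 and a median log2 fold change of -0.997. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1e-12 for PFKFB4, 4.02e-12 for BNIP3, 3.99e-11 for NDRG1 and 1.12e-10 for EGLN3. The list stood apart from other genes (camera, adjusted p = 1.92e-96, and adjusted p = 0.000249 with an estimated correlation). PFKFB4 lies on chromosome 3 from 48517684 to 48562015, BNIP3 on chromosome 10 from 131966455 to 131982013 and NDRG1 on chromosome 8 from 133237175 to 133302022 (hg38). With trends on GC content and length removed, the median of the list was -1.03.

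Several of the most reduced genes lay outside that list, which was fixed beforehand. Whether they fell as part of the same response was not tested. LOX, which cross-links collagen, went from 156 ± 2.66 to 34.3 ± 2.55 CPM (SD, n = 3), a log2 fold change of -2.19 ± 0.13 (SE). IGFBP1, an insulin-like growth factor binding protein of hepatocytes, went from 2005 ± 98.7 to 706 ± 46.6 CPM (-1.51 ± 0.08). TSPEAR fell by 2.91 ± 0.14 on the log2 scale. Among the genes that rose most were NOS3, the endothelial nitric oxide synthase, from 13.7 ± 0.661 to 44.9 ± 3.90 CPM (1.71 ± 0.10), and CXCL8, a neutrophil-attracting chemokine, from 2.25 ± 0.458 to 8.34 ± 1.57 CPM (1.89 ± 0.22). Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 5.23e-08 for LOX, 1.98e-11 for IGFBP1, 1.12e-11 for TSPEAR, 1.12e-10 for NOS3 and 2.17e-06 for CXCL8.

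Lipid genes did not move as 1 group. PLIN2 (ENSG00000147872, chromosome 9 from 19108375 to 19149290), which encodes the main coat protein of hepatocyte lipid droplets, was lower with oleic acid, at 1054 ± 15.9 CPM in control and 491 ± 16.4 with oleic acid (SD, n = 3), a log2 fold change of -1.10 ± 0.07 (SE). HILPDA, an inhibitor of triglyceride lipolysis (-1.25 ± 0.16), and ANGPTL4, an inhibitor of lipoprotein lipase (-0.90 ± 0.16), fell as well. CPT1A, the carnitine acyltransferase that commits fatty acids to mitochondrial oxidation, went from 89.7 ± 5.05 to 129 ± 2.94 CPM (0.53 ± 0.07), and ACSL1, which activates fatty acids, from 34.7 ± 1.06 to 58.7 ± 0.668 CPM (0.76 ± 0.08). CREB3L3, a hepatic transcription factor (0.92 ± 0.11), CIDEC, a lipid droplet fusion protein (0.81 ± 0.17), and DGAT2, which makes triglyceride (0.49 ± 0.09), also rose. FABP1, the liver fatty acid binding protein, went from 119.6 ± 1.88 to 54.6 ± 3.36 CPM (-1.13 ± 0.09). PDK4, an inhibitor of pyruvate dehydrogenase, had 3, 1 and 1 reads in the control libraries and 19, 9 and 12 with oleic acid. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 4.14e-10 for PLIN2, 6.67e-06 for HILPDA, 0.000341 for ANGPTL4, 1.59e-05 for CPT1A, 6.86e-07 for ACSL1, 2.49e-06 for CREB3L3, 0.00154 for CIDEC, 0.000426 for DGAT2, 8.18e-09 for FABP1 and 0.00829 for PDK4, whose call was lost with limma on FPKM. CD36, a fatty acid transporter (0.99 ± 0.38, adjusted p = 0.0789), FASN, the fatty acid synthase (-0.20 ± 0.08, 0.10), PPARA, a fatty acid receptor (0.05 ± 0.09, 0.766), CYP1A1 (-0.23 ± 0.15, 0.306) and DDIT3, a stress transcription factor (-0.32 ± 0.23, 0.367) did not pass that edgeR test. FASN did without sesamin replicate 1 (adjusted p = 0.0379) or 3 (0.021), with only the 6 libraries compared (0.0045) and with trends on GC content and length removed (0.000165), as did CD36 with those trends removed (0.0293). CYP3A4 had too few reads to be tested (0 to 4 per library).

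Counted by list, 10 of 24 PPAR targets rose and 6 fell (11 and 7 adjusted over the list alone, median log2 fold change 0.20, camera, adjusted p = 0.526, and adjusted p = 0.654 with an estimated correlation). Of 31 fatty acid oxidation genes, 5 rose (CPT1A, CRAT, SLC25A20, ACADVL, HADHB) and 2 fell (ETFB, PEX11A), the same counts adjusted over the list alone. Its median log2 fold change was 0.04 (camera, adjusted p = 0.589, and adjusted p = 0.743 with an estimated correlation), and 9 were higher and 3 lower with trends on GC content and length removed (camera adjusted p = 0.471). In triglyceride synthesis 6 of 17 rose and 1 fell (LPIN3), or 6 and 2 adjusted over the list alone. The list median was 0.11 (camera, adjusted p = 0.154, and adjusted p = 0.234 with an estimated correlation), and camera gave adjusted p = 0.0283 with no count filter. In lipid droplet and lipolysis genes, 2 of 18 rose (CIDEC, PNPLA2) and 4 fell (PLIN2, HILPDA, PNPLA3, ACSL3), the same counts adjusted over the list alone. The median log2 fold change was 0.00 (camera, adjusted p = 0.0984, and adjusted p = 0.189 with an estimated correlation).

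Genes of cholesterol synthesis were lower with oleic acid, as were 8 of 19 genes of fatty acid synthesis and desaturation. DHCR7, the reductase of the last step to cholesterol, went from 260.2 ± 16.4 to 151 ± 5.65 CPM (SD, n = 3), a log2 fold change of -0.79 ± 0.07 (SE). Of the 25 measured genes of cholesterol synthesis and uptake, 19 fell, as did 19 adjusted over the list alone, and the other 6 did not pass, with a median of -0.50. SCD, the stearoyl-CoA desaturase, went from 2481 ± 8.26 to 1414 ± 47.6 CPM (-0.81 ± 0.06), and SREBF1, a transcription factor of lipid synthesis, and FADS2, a fatty acid desaturase, fell by 0.63 ± 0.09 and 0.68 ± 0.09 on the log2 scale. Of 19 genes of fatty acid synthesis and desaturation, 8 fell and 2 rose (MLXIPL, MID1IP1), or 9 and 3 adjusted over the list alone. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.96e-08 for DHCR7, 7.32e-09 for SCD, 4.91e-05 for SREBF1 and 1.19e-05 for FADS2. By camera, adjusted p was 9.33e-16 for the cholesterol list (0.0134 with an estimated correlation, as an adjusted p) and 0.00369 for the fatty acid list, with adjusted p = 0.139 with an estimated correlation. DHCR7 lies on chromosome 11 from 71428193 to 71452868 (hg38).

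Targets of the tumour suppressor p53 were higher with oleic acid, and most changed genes of the hepatocyte identity and lipoprotein secretion lists were lower. CDKN1A, the cyclin-dependent kinase inhibitor p21 (chromosome 6 from 36676460 to 36687337, hg38), went from 213 ± 7.01 to 442 ± 19.4 CPM (SD, n = 3), a log2 fold change of 1.05 ± 0.07 (SE), and PLK3, a stress-activated kinase, from 32.6 ± 3.64 to 65.9 ± 2.74 CPM (1.01 ± 0.09). Of 22 measured p53 targets 15 rose, as did 15 adjusted over the list alone, and the other 7 did not pass. The median was 0.36 (camera, adjusted p = 1.9e-08, and adjusted p = 0.00963 with an estimated correlation). TF, which encodes transferrin, went from 1995 ± 53 to 1051 ± 17 CPM (-0.93 ± 0.06), and ALB, serum albumin, from 4564 ± 199 to 2670.0 ± 142 CPM (-0.77 ± 0.07). In the hepatocyte identity list 12 of 27 fell and 4 rose (ASS1, FGB, CEBPA, CPS1), or 13 and 4 adjusted over the list alone. Its median log2 fold change was -0.16 (camera, adjusted p = 0.000168, and adjusted p = 0.124 with an estimated correlation). MTTP, which loads lipid onto apolipoprotein B, fell by 1.10 ± 0.13 on the log2 scale, and in the lipoprotein secretion list 7 of 18 fell and 1 rose (PLTP), or 9 and 2 adjusted over the list alone. The list median was -0.26 (camera, adjusted p = 0.0157, and adjusted p = 0.125 with an estimated correlation). Among 13 mitochondrially encoded genes 5 rose (MT-CO3, MT-CO2, MT-ND1, MT-CYB, MT-CO1), 7 adjusted over the list alone, beside the higher mitochondrial share of counts given above (median 0.34, camera, adjusted p = 0.000745, and adjusted p = 0.354 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 2.01e-09 for CDKN1A, 7.24e-08 for PLK3, 6.74e-10 for TF, 7.24e-08 for ALB and 1.79e-06 for MTTP. In edgeR the call of MT-ND1 was lost without control replicate 1 (adjusted p = 0.0522), and that of MT-CYB without control replicate 1 (0.0633), control replicate 2 (0.058) or oleic acid replicate 3 (0.0631). Both calls were lost with trends on GC content and length removed (adjusted p = 0.0699 and 0.0891) while the log2 fold changes went from 0.57 to 0.61 for MT-ND1 and from 0.46 to 0.49 for MT-CYB, and the list median was 0.41 (camera, adjusted p = 0.00198).

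In all, 2494 of 14054 genes changed with oleic acid, 1333 higher and 1161 lower, and 424 of them by at least 2-fold (198 higher, 226 lower). Without oleic acid replicate 2 the count was 1632, with only the 6 libraries compared it was 3780, and limma on log2(FPKM + 1) without a filter called 1498. Groups did not overlap in 5414 genes (38.5%), where chance gives 10%, and every changed gene given with a value above was among them. Across genes, which are not independent replicates, log2 fold change and GC content had a Spearman correlation of 0.228, and with trends on GC content and length removed 2208 of the 2494 genes were called with the same sign. Of 34 lists, 17 passed camera with the preset correlation (8 higher, 9 lower), and hypoxia and glycolysis, cholesterol, and p53 targets also did with an estimated correlation.

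**Figure D3:**
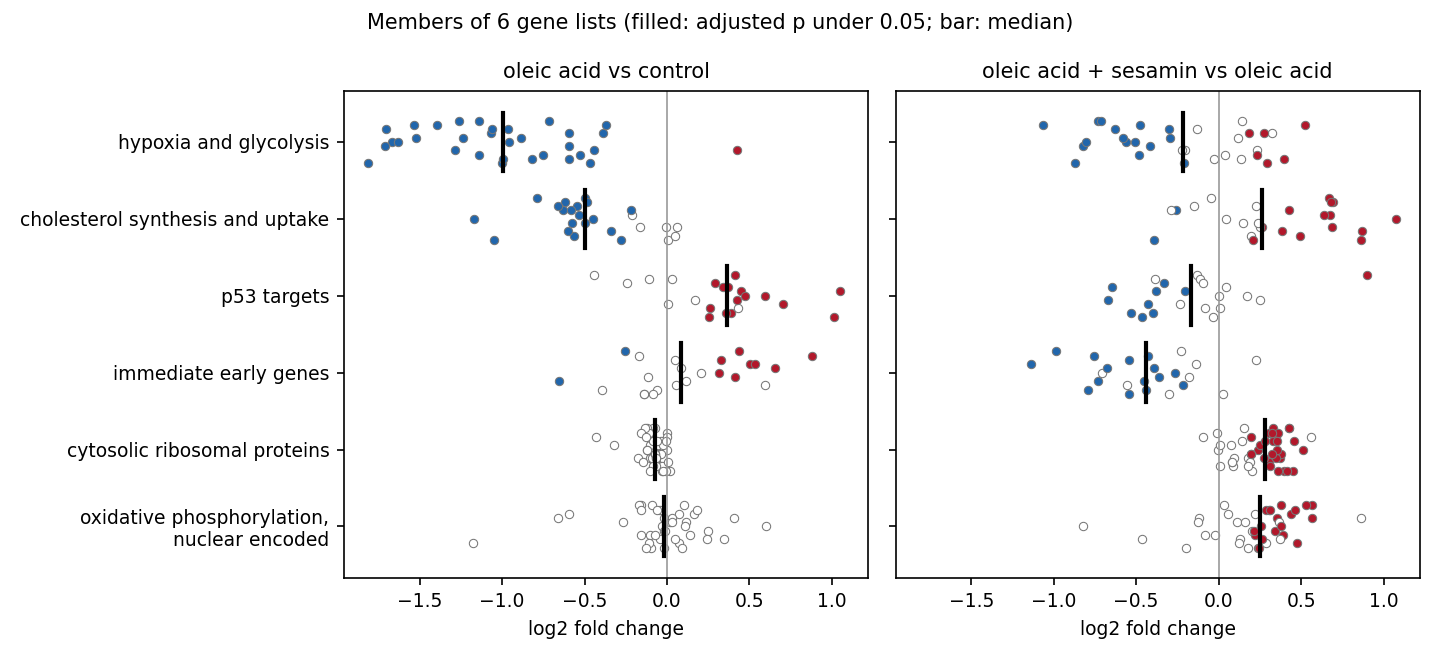
Log2 fold changes (x axis) of the members of 6 gene lists (y axis) for oleic acid against control and sesamin against oleic acid. There is 1 point per gene, filled where adjusted p was under 0.05, with a bar at the median. With oleic acid the hypoxia median lay at -0.997, the cholesterol median at -0.50 and the p53 median at 0.36, and with sesamin the ribosomal protein median lay at 0.28 and the immediate early gene median at -0.44.

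**Figure D4:**
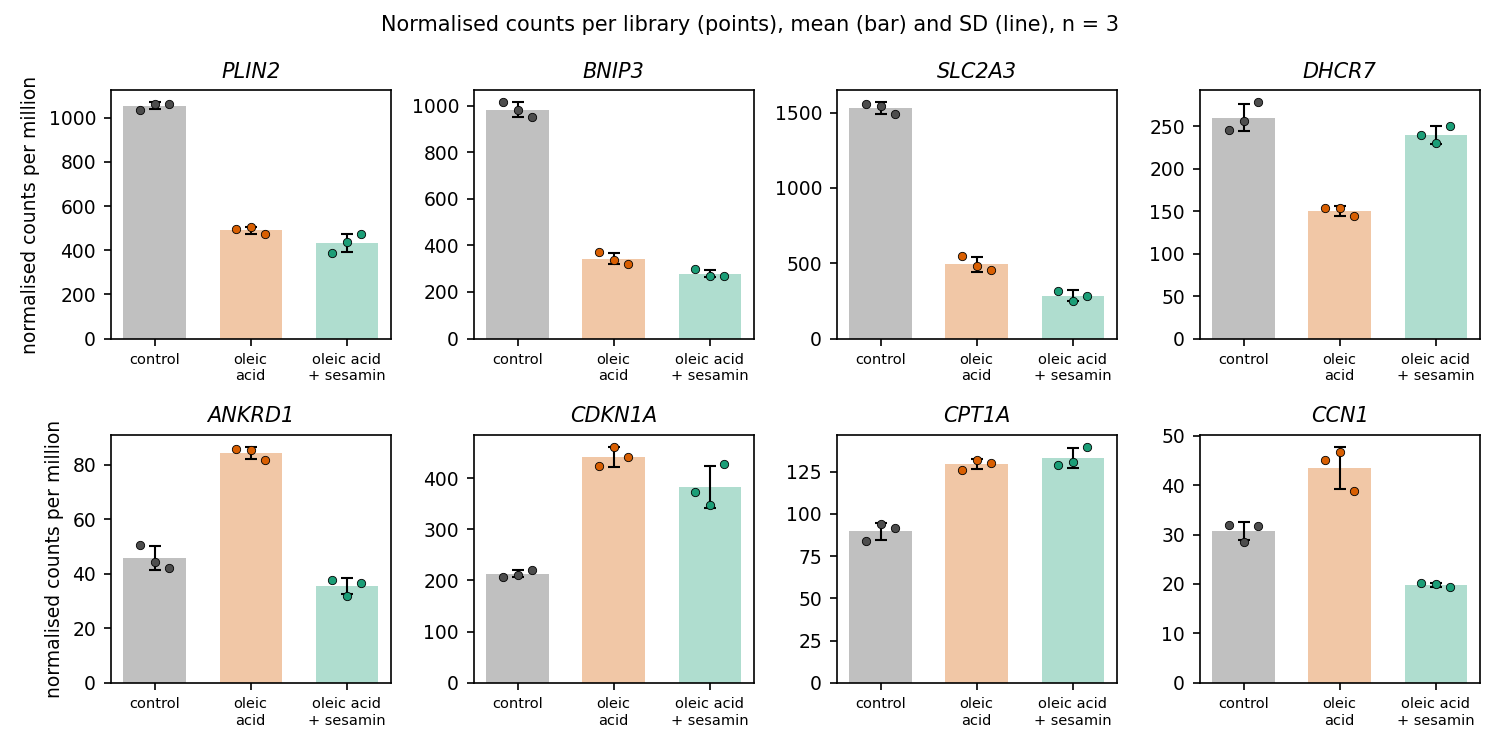
Normalised CPM (y axis) of 8 named genes in each of the 9 libraries, by group (x axis), with a bar at the mean and a line for the SD (n = 3). PLIN2, BNIP3 and SLC2A3 were lower in both groups given oleic acid than in control, while DHCR7 was lowest with oleic acid alone.

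The comparison of sesamin with oleic acid alone asks how libraries with both compounds differed from those with the fatty acid alone. Genes of cholesterol synthesis were higher with sesamin, as were 8 of 19 genes of fatty acid synthesis and desaturation. MVK, the mevalonate kinase, stood at 29.4 ± 2.06 CPM with oleic acid and 53.7 ± 2.81 with sesamin (SD, n = 3), a log2 fold change of 0.87 ± 0.09 (SE). DHCR7 rose by 0.67 ± 0.07 on the log2 scale, FASN went from 1200.0 ± 17.7 to 1883 ± 238 CPM (0.65 ± 0.08), and ACSS2, which makes acetyl-CoA from acetate, and SCD had log2 fold changes of 0.61 ± 0.08 and 0.27 ± 0.06. Of 25 cholesterol genes 14 rose and 2 fell, LBR among them, or 16 and 3 adjusted over the list alone (median 0.27, camera, adjusted p = 4.76e-12, and adjusted p = 0.0793 with an estimated correlation). Of 19 genes of fatty acid synthesis 8 rose and 3 fell (ELOVL5, ELOVL2, ELOVL7), or 9 and 3 adjusted over the list alone. The median log2 fold change was 0.10 (camera, adjusted p = 0.00387, and adjusted p = 0.190 with an estimated correlation). APOA1, the main protein of high-density lipoprotein, went from 516 ± 28.4 to 791 ± 95.1 CPM (0.62 ± 0.08), and in lipoprotein secretion 7 of 18 rose, as did 7 adjusted over the list alone. The median was 0.26 (camera, adjusted p = 0.00246, and adjusted p = 0.135 with an estimated correlation). Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.78e-06 for MVK, 3.78e-06 for DHCR7, 7.14e-05 for FASN, 9.91e-05 for ACSS2, 0.00431 for SCD and 4.2e-05 for APOA1. With trends on GC content and length removed, the medians were 0.38 for cholesterol, 0.11 for fatty acid synthesis (5 higher, 1 lower) and 0.08 for lipoprotein secretion (4 higher).

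PLIN2 did not pass the threshold between sesamin and oleic acid. The values were 491 ± 16.4 CPM with oleic acid and 433 ± 41.5 with sesamin (SD, n = 3), a log2 fold change of -0.18 ± 0.07 (SE), with adjusted p = 0.0660 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In edgeR adjusted p for PLIN2 was 0.0141 without sesamin replicate 3, 0.0392 with library totals and 0.0243 with trends on GC content and length removed. CPT1A (0.04 ± 0.07, edgeR adjusted p = 0.724), PDK4 (-0.02 ± 0.51, 0.988), CD36 (-0.03 ± 0.35, 0.965) and PPARA (-0.11 ± 0.09, 0.436) did not pass that test either. ANGPTL4 fell by 1.20 ± 0.18 on the log2 scale and TXNIP, an inhibitor of thioredoxin, went from 708 ± 50.0 to 421 ± 40.3 CPM (-0.75 ± 0.07), while FABP1 went from 54.6 ± 3.36 to 85.6 ± 11 CPM (0.65 ± 0.09; edgeR adjusted p = 0.000213, 3.21e-06 and 8.03e-05 in that order). Among lipid droplet genes 4 rose (AUP1, METTL7B, PNPLA3, FITM2) and 2 fell (RAB18, HILPDA), or 5 and 3 adjusted over the list alone. Its median log2 fold change was 0.17 (camera, adjusted p = 0.217, and adjusted p = 0.323 with an estimated correlation). In edgeR the call of HILPDA was lost without oleic acid replicate 1 (adjusted p = 0.18), sesamin replicate 2 (0.06) or sesamin replicate 3 (0.0656), those of METTL7B and RAB18 without oleic acid replicate 1 (0.0531 and 0.0507) or sesamin replicate 2 (0.0511 and 0.0538), and with trends on GC content and length removed the calls of RAB18 (-0.04, adjusted p = 0.757), METTL7B (0.33, 0.0882) and AUP1 (0.06, 0.471) were lost.

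Ribosomal protein genes were higher with sesamin, as were 20 of 40 nuclear genes of the respiratory chain. RPS2, a protein of the small ribosomal subunit, went from 2171 ± 139 to 2968 ± 232 CPM (SD, n = 3), a log2 fold change of 0.45 ± 0.07 (SE), and RPLP0, of the ribosomal stalk, from 2338 ± 125 to 3001 ± 205 CPM (0.36 ± 0.07). Of 47 cytosolic ribosomal protein genes 30 rose, or 35 adjusted over the list alone (median 0.28). ATP5MC3, a subunit of the ATP synthase ring, went from 177 ± 6.34 to 262 ± 37.1 CPM (0.57 ± 0.08), and of 40 nuclear-encoded oxidative phosphorylation genes 20 rose, as did 20 adjusted over the list alone (median 0.25). ETFB, which passes electrons from acyl-CoA dehydrogenases, went from 63.3 ± 0.845 to 95.2 ± 10.3 CPM (0.59 ± 0.08), and ECHS1, the short-chain enoyl-CoA hydratase, rose by 0.45 ± 0.07 on the log2 scale. Of 31 fatty acid oxidation genes 10 rose, and 11 rose and 1 fell adjusted over the list alone (median 0.21). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.000491 for RPS2, 0.00153 for RPLP0, 0.000159 for ATP5MC3, 8.77e-05 for ETFB and 0.000424 for ECHS1. By camera, adjusted p was 1.29e-13 for ribosomal proteins, 2.59e-07 for oxidative phosphorylation and 0.000769 for fatty acid oxidation, and adjusted p = 0.286, 0.209 and 0.135 with an estimated correlation. With trends on GC content and length removed, 47 ribosomal protein genes had a median of 0.20 with 22 called, oxidative phosphorylation 0.23 with 16 called, and fatty acid oxidation 0.16 with 7 called.

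Immediate early and mitotic genes were lower with sesamin, as were 6 of 14 heat shock genes. CCN1, a matricellular growth factor target (chromosome 1 from 85580761 to 85584589, hg38), went from 43.6 ± 4.25 to 19.8 ± 0.444 CPM (SD, n = 3), a log2 fold change of -1.14 ± 0.10 (SE), DUSP1, a MAP kinase phosphatase, from 56.9 ± 4.53 to 28.7 ± 2.16 CPM (-0.99 ± 0.09), and JUN, a subunit of AP-1, from 232 ± 7.13 to 140.1 ± 12 CPM (-0.73 ± 0.07). Of 23 immediate early genes 15 fell, or 16 adjusted over the list alone. The list median was -0.44 (camera, adjusted p = 7.72e-15, and adjusted p = 0.0802 with an estimated correlation). CDK1, the mitotic cyclin-dependent kinase, went from 195 ± 11.6 to 137 ± 14.2 CPM (-0.51 ± 0.08), and 14 of 25 mitotic genes fell, or 17 adjusted over the list alone (median -0.35, camera, adjusted p = 2.21e-07, and adjusted p = 0.135 with an estimated correlation). GDF15, a stress cytokine that p53 induces, went from 1087 ± 62.0 to 751 ± 7.70 CPM (-0.53 ± 0.07), and of 22 p53 targets 9 fell and 1 rose (SESN2), or 11 and 3 adjusted over the list alone. The median log2 fold change was -0.17 (camera, adjusted p = 0.00214, and adjusted p = 0.0984 with an estimated correlation). HSPH1, a chaperone of the Hsp110 family, fell by 0.55 ± 0.08 on the log2 scale, and 6 of 14 heat shock genes fell, or 7 adjusted over the list alone. The median was -0.15 (camera, adjusted p = 0.0102, and adjusted p = 0.209 with an estimated correlation). Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 9.44e-07 for CCN1, 1.09e-06 for DUSP1, 3.21e-06 for JUN, 0.000326 for CDK1, 3.67e-05 for GDF15 and 0.000181 for HSPH1. In edgeR the call of SESN2 was lost without oleic acid replicate 1 (adjusted p = 0.0691) or 3 (0.0529). With trends on GC content and length removed, 0 p53 targets rose and 8 fell. Mitotic genes had a median GC content of 42.5%, and with trends on GC content and length removed their median was -0.21 with 13 called.

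The hypoxia list moved in both directions with sesamin. SLC2A3, a high-affinity glucose transporter, went from 494 ± 49.5 to 283 ± 36.1 CPM (SD, n = 3), a log2 fold change of -0.80 ± 0.09 (SE), and CA9, a carbonic anhydrase (-1.07 ± 0.16), and ADM, which encodes adrenomedullin (-0.87 ± 0.11), fell as well. SLC2A1, the glucose transporter of most cells, went from 1865 ± 129 to 2676 ± 130.4 CPM (0.52 ± 0.07). Of 32 members 16 fell and 6 rose, or 16 and 7 adjusted over the list alone (median -0.22, camera, adjusted p = 0.000495, and adjusted p = 0.190 with an estimated correlation), and those that rose were SLC2A1 and the glycolytic enzymes TPI1, GAPDH, PFKL, PKM and GPI. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.18e-05 for SLC2A3, 0.000181 for CA9, 3.72e-05 for ADM and 7.54e-05 for SLC2A1. HMOX1, heme oxygenase, rose by 0.50 ± 0.09 on the log2 scale (edgeR adjusted p = 0.000917), and the value of CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was 0.60 ± 0.15 (edgeR adjusted p = 0.00682, or 0.0566 without oleic acid replicate 1). DDIT3 had a value of 0.42 ± 0.22 (edgeR adjusted p = 0.184).

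With sesamin 3129 of 14054 genes changed against oleic acid, 1471 higher and 1658 lower, and 76 of them by at least 2-fold. The count was 1426 without oleic acid replicate 1, 1835 without oleic acid replicate 3 and 1892 without sesamin replicate 2. On log2(FPKM + 1), limma called 2082 genes with a filter on low FPKM and 635 without. Groups did not overlap in 5321 genes (37.9%), where chance gives 10%. Across genes, log2 fold change had a Spearman correlation of 0.443 with GC content and of -0.265 with gene length, and the median log2 fold change was -0.22 in the fifth of lowest and 0.16 in the fifth of highest GC content. With both trends removed 2096 genes were called, 1428 of them (45.6% of the 3129) with the same sign as before. Of 34 lists 11 passed camera with the preset correlation (6 higher, 5 lower), and 0 did with an estimated correlation, where 6 had an unadjusted p under 0.05.

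Whether sesamin undid the changes of oleic acid was read from the 685 genes called in both comparisons. AREG, an epidermal growth factor receptor ligand, stood at 9.62 ± 1.73 CPM in control, 26.1 ± 1.79 with oleic acid and 13.8 ± 0.855 with sesamin (SD, n = 3), and ANKRD1, a target of mechanical signalling, at 45.7 ± 4.48, 84.3 ± 2.37 and 35.4 ± 2.96 CPM. DHCR7 had 260.2 ± 16.4, 151 ± 5.65 and 239.7 ± 10.0 CPM in the same order. Other genes went further from control with sesamin, among them ERRFI1, a feedback inhibitor of the epidermal growth factor receptor, at 1667 ± 38.8, 916 ± 62.3 and 517 ± 71.0 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p with sesamin was 8.77e-05 for AREG (-0.92 ± 0.13, SE), 9.65e-08 for ANKRD1 (-1.25 ± 0.09) and 4.35e-06 for ERRFI1 (-0.83 ± 0.08). In the cholesterol list 10 of the 19 genes that fell with oleic acid rose with sesamin, in fatty acid synthesis 5 of 10 changed genes moved back (ACSS2, FADS2, PNPLA3, SCD, SREBF1), in p53 targets 8 of 15, and in hypoxia and glycolysis 6 of 32 moved back and 16 moved on. In edgeR the sesamin call of SREBF1 was lost without oleic acid replicate 1 (adjusted p = 0.0571).

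Over all genes 354 of the 2494 changed with oleic acid moved back with sesamin (203 up then down, 151 down then up) and 331 moved on in the same direction (122 up, 209 down). Independent lists of these sizes would share 278.8 genes with opposite and 276.5 with equal signs. A simulated group that did not differ from oleic acid had 0.96 genes called against it on average, so its 0.52 genes with opposite signs were close to 0 by construction. Of the genes called with oleic acid, 62.7% had the opposite sign in that simulation and 49% in the data, or 61.5% in the data once trends on GC content and length were removed. The simulation drew genes independently and called 3465 genes with oleic acid on average, against 2494 in the data. These shares therefore cover different sets of genes. The covariance of the log2 fold changes was -0.0232. It was -0.0248 (SD 0.00159) when simulated with no sesamin effect, and the spread of the oleic acid libraries gave -0.0231. Their correlation was -0.148, against -0.226 in that simulation. After removal of trends on GC content and length the covariance was -0.0333, against -0.0228 from the spread of the oleic acid libraries, and the correlation was -0.236. The 3 oleic acid libraries cannot be divided into parts of at least 2 libraries, so part of the excess of opposite signs over independent lists may come from the shared libraries. Noise in those libraries favours opposite signs, so it does not account for the excess of equal signs (331 against 276.5), whose cause was not tested. More genes moved on than back without control replicate 3 (335 against 255), without sesamin replicate 1 (649 against 566) and by DESeq2 (386 against 367). The counts back and on were 287 and 192 without control replicate 1, 210 and 183 without control replicate 2, 244 and 198 without sesamin replicate 2, and 546 and 237 with trends on GC content and length removed. Without oleic acid replicate 1, 2 or 3 they were 167 and 128, 236 and 176, and 200 and 151. Of the 2494 genes 1901 (76.2%) were also called between sesamin and control with the same sign. Both comparisons use the same control libraries, which by itself favours equal signs, and no simulated value was computed for this count.

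**Figure D5:**
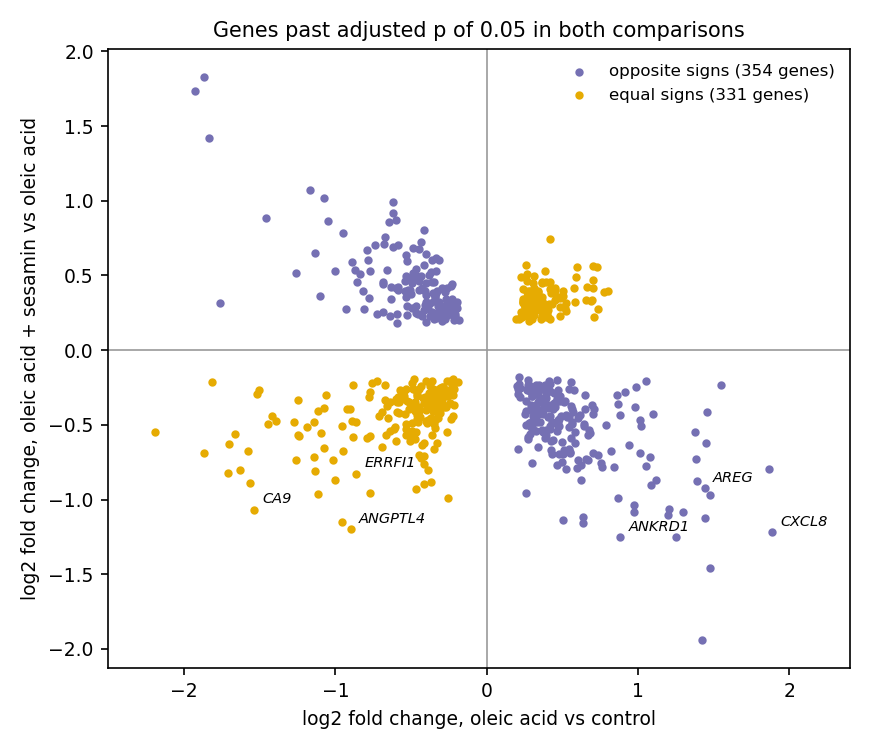
Log2 fold change with oleic acid against control (x axis) and with sesamin against oleic acid (y axis) for the 685 genes called in both comparisons, 1 point per gene. In 354 genes the signs were opposite and in 331 equal.

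The comparison of sesamin with control gives the state of the treated cells against cells given neither compound. Genes of glycolysis and the hypoxia response were lower in the treated cells. CA9 (chromosome 9 from 35673918 to 35681159, hg38) stood at 39.4 ± 5.11 CPM in control and 6.46 ± 0.675 with sesamin (SD, n = 3), a log2 fold change of -2.60 ± 0.15 (SE). PFKFB3, an activator of glycolysis, stood at 169 ± 6.63 and 29.1 ± 4.02 CPM (-2.54 ± 0.12). CP, which encodes ceruloplasmin and was on the acute phase list, stood at 125 ± 7.56 and 26.3 ± 5.32 CPM (-2.25 ± 0.11). PLIN2 fell by 1.28 ± 0.07 and SCD by 0.54 ± 0.06 on the log2 scale, and CPT1A and FASN rose by 0.57 ± 0.07 and 0.45 ± 0.08. NOS3 went from 13.7 ± 0.661 to 46.1 ± 0.947 CPM (1.75 ± 0.10). The values were 0.01 ± 0.09 for HMOX1, 0.96 ± 0.39 for CD36 and -0.06 ± 0.10 for PPARA, and none of these 3 passed edgeR's test (adjusted p = 0.920, 0.0508 and 0.654), while with trends on GC content and length removed HMOX1 (-0.31, adjusted p = 0.00388) and CD36 (adjusted p = 0.0061) did. CD36 also passed edgeR's test without control replicate 1 (adjusted p = 0.0494). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 7.6e-11 for CA9, 5.76e-10 for PFKFB3, 1.87e-11 for CP, 2.9e-11 for PLIN2, 1.39e-06 for SCD, 3.62e-06 for CPT1A, 0.000369 for FASN and 4.93e-11 for NOS3. Of 32 hypoxia and glycolysis genes 29 fell, and 29 fell and 1 rose adjusted over the list alone. Its median log2 fold change was -1.11 (camera, adjusted p = 3.66e-71, and adjusted p = 0.00123 with an estimated correlation).

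The lists that rose against control included 24 of 47 ribosomal protein genes (26 adjusted over the list alone, median 0.22, camera, adjusted p = 0.00110, and adjusted p = 0.575 with an estimated correlation) and 19 of 40 oxidative phosphorylation genes (the same count adjusted over the list alone, median 0.21, camera, adjusted p = 0.00171, and adjusted p = 0.442 with an estimated correlation). Once trends on GC content and length were removed, 17 ribosomal protein genes were higher and 3 lower, with a median of 0.13 (camera adjusted p = 0.00895). In cholesterol synthesis and uptake 5 rose, among them TM7SF2, PMVK, MVK and EBP, and 10 fell, the same counts adjusted over the list alone. The list median was -0.12 (camera, adjusted p = 0.255, and adjusted p = 0.567 with an estimated correlation), and with those trends removed 1 was higher and 10 lower (median -0.15). Among immediate early genes 13 of 23 fell and 3 rose (EGR1, IER5, DUSP5), or 13 and 4 adjusted over the list alone. The median log2 fold change was -0.44, and -0.48 to -0.19 over left-out libraries (camera, adjusted p = 0.00110, and adjusted p = 0.377 with an estimated correlation). Among mitotic genes 16 of 25 fell and 1 rose (CDC20), or 17 and 1 adjusted over the list alone (median -0.32, camera, adjusted p = 0.0137, and adjusted p = 0.442 with an estimated correlation), and with trends on GC content and length removed 12 fell, with a median of -0.14 (camera adjusted p = 0.0848). In p53 targets 9 of 22 rose and 3 fell (MDM2, TNFRSF10B, RRM2B), or 10 and 5 adjusted over the list alone. The median was 0.21 (camera, adjusted p = 0.0776, and adjusted p = 0.291 with an estimated correlation), and camera gave adjusted p = 0.047 without control replicate 1, 0.048 without sesamin replicate 2 and 0.0167 with no count filter. Once trends on GC content and length were removed, 6 p53 targets were higher and 3 lower, with a median of 0.12 (camera adjusted p = 0.262). Of 31 fatty acid oxidation genes 12 rose and 4 fell, among them ETFB, PEX11A and ACADSB, or 14 and 4 adjusted over the list alone, with a median of 0.21 (camera, adjusted p = 0.0105, and adjusted p = 0.291 with an estimated correlation). Of 13 mitochondrially encoded genes 7 rose, or 8 adjusted over the list alone. Their median was 0.39, and 0.18 to 0.52 over left-out libraries (camera, adjusted p = 0.00110, and adjusted p = 0.442 with an estimated correlation).

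Against control 5815 of 14054 genes changed, 2917 higher and 2898 lower, and 643 of them by at least 2-fold. Groups did not overlap in 6859 genes (48.8%), where chance gives 10%, and limma on log2(FPKM + 1) without a filter called 3743 genes. Log2 fold change and GC content had a Spearman correlation of 0.495 across genes, the strongest of the 3 comparisons, with a median of -0.31 in the fifth of lowest and 0.30 in the fifth of highest GC content. With trends on GC content and length removed 4405 genes were called, 3040 of them (52.3% of the 5815) with the same sign as before and 29 with the opposite sign. Of 34 lists 11 passed camera (7 higher, 4 lower), and with an estimated correlation only hypoxia and glycolysis did. That more genes passed against control than in either other comparison was not tested as a difference.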

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

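The alternatives that used library totals without TMM factors, RLE factors for the gene lists, recomputed annotation terms, or offsets that removed the trends on GC content and gene length were chosen after the data had been seen. With RLE factors, DESeq2, library totals, no count filter, the stricter filter, limma on log2(FPKM + 0.1) or the trends removed, the counts of changed genes stayed within 1.5 times in each of the 3 comparisons. The genes themselves differed more with the trends removed. Calls kept with the same sign were then 88.5% with oleic acid, 45.6% for sesamin against oleic acid and 52.3% for sesamin against control. Leaving out each library in turn moved the count of changed genes between 1632 and 3254 with oleic acid and between 1426 and 4452 for sesamin against oleic acid, the count of genes that moved back between 167 and 566, and the count of annotation terms between 47 and 176 for sesamin against oleic acid and between 72 and 150 against control. The fit to the 6 libraries compared called 3780 genes with oleic acid. On log2(FPKM + 1) with no filter, limma called 1498 genes with oleic acid, 635 for sesamin against oleic acid and 3743 for sesamin against control, and with a mean FPKM of at least 0.1 it called 2082 for sesamin against oleic acid. Against a 1.5-fold change, glmTreat called 229, 6 and 358 genes in the same order, where a fold bound on top of the test leaves fewer genes by construction. With a change of at least 2-fold the counts were 424, 76 and 643 at an adjusted p under 0.05, and 583, 153 and 752 at an unadjusted p under 0.05. Among the 424 genes changed at least 2-fold with oleic acid, 38 moved back and 32 moved on. Over all called genes 354 moved back and 331 moved on, 546 and 237 did with trends removed, and 0.52 moved back in simulated groups with no sesamin effect, where 0.96 genes were called on average. Library totals put 62.0% of calls higher with oleic acid (53.4% with TMM) and 38.9% higher for sesamin against oleic acid (47.0% with TMM), and no scaling moved the median of all genes by more than 0.03. With an estimated correlation 3 lists passed with oleic acid (hypoxia and glycolysis, cholesterol, p53 targets), 0 for sesamin against oleic acid and 1 against control (hypoxia and glycolysis). By fry, which tests a list on its own, 20 and 27 lists moved 1 way in the sesamin comparisons (22 with oleic acid), and 31, 32 and 33 changed in either direction. The sign of HMOX1 between sesamin and control turned from 0.01 to -0.31 (adjusted p = 0.00388 by edgeR) with trends removed. Where no cause is given, the cause was not tested.

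The replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at -0.05 to 0.12 over genes, 1 of 9 correlations lay above 0.1, and 3 libraries correlated best with their own number. With the replicate number as a block, 2942, 3827 and 6166 genes were called, 476 moved back and 523 moved on, which turned the balance. With the block the call of MT-CYB with oleic acid was lost (edgeR adjusted p = 0.0747), PLIN2 passed between sesamin and oleic acid (0.0428), and the PXR and CAR list with oleic acid had a camera adjusted p of 0.0508. Among the called genes from the naming rule that were followed through these settings, DESeq2 lost the call of 1 (of 29 for sesamin against control), and removing the trends lost 2 of 89, 9 of 70 and 2 of 29 in the 3 comparisons. Depth limits the low genes, such as PDK4, whose call rests on 5 reads in the control libraries together.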

Other observations

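The tests of culture conditions and of exchanged labels, and the values with trends on GC content and length removed, were chosen only after the results they bear on had been seen. Beyond lipid, hypoxia and p53 genes, stress and detoxification genes differed between the libraries labelled oleic acid and control. Of 27 NRF2 targets 10 rose and 2 fell (HMOX1, SLC7A11), or 11 and 2 adjusted over the list alone (median 0.15, camera, adjusted p = 0.00369, and adjusted p = 0.141 with an estimated correlation), and the median was 0.085 with trends on GC content and length removed. TXNRD1, a thioredoxin reductase, went from 422 ± 18.1 to 609 ± 16.6 CPM (SD, n = 3). Of 11 interferon response genes 6 rose, or 7 adjusted over the list alone (median 0.40, camera, adjusted p = 0.000896, and adjusted p = 0.124 with an estimated correlation), with OAS1, an antiviral synthetase, at 11.3 ± 0.953 and 18.4 ± 0.15 CPM. Against control, 8 of them were higher with sesamin, as were 8 adjusted over the list alone (median 0.85, camera, adjusted p = 0.00110, and adjusted p = 0.291 with an estimated correlation), and the median was 0.56 with trends on GC content and length removed. In the same comparison 14 NRF2 targets rose and 4 fell (ABCC2, GCLC, SLC7A11, UGDH), or 15 and 4 adjusted over the list alone (median 0.22, camera, adjusted p = 0.00164, and adjusted p = 0.291 with an estimated correlation). Of 28 autophagy and lysosome genes 7 rose and 2 fell (NPC1, ATG9A), or 11 and 2 adjusted over the list alone (median 0.21, camera, adjusted p = 0.00793, and adjusted p = 0.125 with an estimated correlation). Against control, 11 of these rose with sesamin and 2 fell (NPC1, LAMP2), or 13 and 2 adjusted over the list alone (median 0.22, camera, adjusted p = 0.0111, and adjusted p = 0.291 with an estimated correlation), and with those trends removed the median was 0.07 (camera adjusted p = 0.0718). In the integrated stress response 7 of 26 fell and 3 rose (GDF15, WARS1, PSAT1), with the same counts adjusted over the list alone (median -0.06, camera, adjusted p = 0.0231, and adjusted p = 0.234 with an estimated correlation), and camera's adjusted p was 0.0528 without control replicate 3, 0.0796 without oleic acid replicate 1 and 0.0546 with no count filter. The median was -0.15 with trends on GC content and length removed, where 8 fell and 5 rose. DDIT4, an inhibitor of mTORC1, went from 469 ± 16.9 to 197 ± 2.07 CPM. In DNA replication 6 of 30 fell and 1 rose (CDT1), or 8 and 1 adjusted over the list alone (median -0.09, camera, adjusted p = 0.0380, and adjusted p = 0.124 with an estimated correlation), and camera's adjusted p was 0.0811 without oleic acid replicate 1 and 0.0592 with library totals, while 10 fell with both trends removed.

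Nuclear receptor lists and markers of other liver cells also held genes that changed with oleic acid. Among 13 PXR and CAR targets 4 rose (ABCC3, SULT2A1, GSTA2, CES2) and 1 fell (SLC13A5), or 6 and 1 adjusted over the list alone. The median was 0.12, and 0.07 to 0.27 over left-out libraries (camera, adjusted p = 0.0439, and adjusted p = 0.193 with an estimated correlation). Camera's adjusted p was 0.0551 without control replicate 1, 0.0619 without control replicate 2 and 0.0922 without oleic acid replicate 1. Among 10 aryl hydrocarbon receptor targets 1 rose (ALDH3A1) and 3 fell (IGFBP1, SLC7A5, CYP1A2), with the same counts adjusted over the list alone (median -0.16, camera, adjusted p = 0.0231, and adjusted p = 0.124 with an estimated correlation), and camera's adjusted p was 0.146 with no count filter. In bile acid synthesis and transport 3 of 13 fell (SLC51A, NR1H4, BAAT), or 5 adjusted over the list alone (median -0.28, camera, adjusted p = 0.00793, and adjusted p = 0.124 with an estimated correlation), and edgeR lost the call of BAAT without control replicate 2 (adjusted p = 0.0991) or oleic acid replicate 1 (0.0545), while 6 fell with both trends removed. Of 6 endothelial markers 2 rose (TIE1, ESAM), or 3 adjusted over the list alone (median 0.70, camera, adjusted p = 0.00290, and adjusted p = 0.107 with an estimated correlation). TIE1 stood at 4.60 ± 0.708 CPM in control, 16.8 ± 0.492 with oleic acid and 9.70 ± 1.84 with sesamin (SD, n = 3), while KDR, PTPRC and CD3E had 0 CPM in every group and COL1A1 0.204, 0.407 and 0.08 CPM of library totals without TMM factors. Among 8 cholangiocyte and progenitor markers 3 rose (KRT19, SPP1, SOX4) and 1 fell (ANXA4), or 4 and 2 adjusted over the list alone (median 0.35, camera, adjusted p = 0.0231, and adjusted p = 0.124 with an estimated correlation), with KRT19 at 388 ± 30.9 and 702 ± 54.2 CPM. Too few fibroblast and immune markers were measured for a list test: ACTA2 rose and PDGFRB fell among 4, and LYZ, at 754 ± 34.4, 456 ± 4.78 and 479 ± 22.1 CPM in the 3 groups, fell among 4. Adjusted over the list alone, the fibroblast counts were the same, while CD3D rose beside the fall of LYZ.

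Other lists did not pass camera with oleic acid. For fatty acid uptake, glucose production and acute phase genes camera pointed down while the median was above 0. Members higher and lower were 3 (ACSL1, SLC27A1, ACOT13) and 3 (FABP1, ACOT1, ACSL3) of 18 for fatty acid uptake and activation (5 and 5 adjusted over the list alone, camera adjusted p = 0.951), 2 (PLTP, NR1H3) and 3 (SCD, SREBF1, ABCA1) of 12 for liver X receptor targets (the same adjusted over the list alone, 0.183), and 1 (G6PC3) and 3 (IGFBP1, PPARGC1A, INSR) of 15 for glucose production (the same adjusted over the list alone, 0.146). Between sesamin and control, 6 glucose production genes fell and 3 rose (G6PC3, PC, GCKR), or 6 and 3 adjusted over the list alone (median -0.36, camera, adjusted p = 0.0415, and adjusted p = 0.442 with an estimated correlation), and camera's adjusted p was 0.0835 without control replicate 3, 0.0636 without sesamin replicate 2, 0.0679 without sesamin replicate 3 and 0.0594 with no count filter. In the unfolded protein response 3 of 21 fell (HSPA5, ERN1, PDIA6), the same adjusted over the list alone (camera adjusted p = 0.0697, but 0.0141 with no count filter, and 6 fell and 1 rose with both trends removed), and in the metallothionein list, which also holds metal transporters, 1 of 8 fell (SLC30A10, a transporter), or 2 adjusted over the list alone (with MT1G, camera adjusted p = 0.214). In acute phase and complement 4 rose (FGG, FGA, FGB, HPX) and 4 fell (CP, FGL1, ITIH3, LEAP2) of 17, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.526), and in the NF-kB and cytokine list 6 rose and 2 fell (CCL20, IER3) of 13, or 6 and 4 adjusted over the list alone (0.635). Of immediate early genes 8 rose and 2 fell (CCN2, DUSP1) of 23, the same adjusted over the list alone (camera adjusted p = 0.0820, but 0.0448 without control replicate 3, 0.0331 without oleic acid replicate 3 and 0.0144 with no count filter). Mitotic genes that rose were CDC20, KIF20A and UBE2C of 25 (camera adjusted p = 0.326), and 1 of 14 heat shock genes rose (BAG3, 0.951), both the same adjusted over the list alone. By edgeR 0 members changed of 40 oxidative phosphorylation genes (4 at an unadjusted p under 0.05, 0 by DESeq2), of 47 ribosomal protein genes (2 unadjusted, 0 by DESeq2) and of 8 histone genes (0 unadjusted, 0 by DESeq2), all also 0 adjusted over the list alone. The camera adjusted p was 0.935 for oxidative phosphorylation, 0.705 for histones and 0.0931 for ribosomal proteins, and for the last 0.0375 without control replicate 1, 0.00807 without oleic acid replicate 2, 0.0155 with no count filter and 0.0262 with trends on GC content and length removed, where 9 ribosomal protein genes were lower.

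Among annotation terms (Fisher's exact test, one-sided, Benjamini-Hochberg adjustment), glycolytic process held 16 genes lower with oleic acid of 26, where 2.21 were expected (adjusted p = 4.31e-08), and cholesterol biosynthetic process 14 of 29 (2.46 expected, adjusted p = 3.01e-05). Response to calcium ion held 16 of 41 genes higher (4.4 expected, adjusted p = 0.00602). For sesamin against oleic acid, structural constituent of ribosome held 71 of 152 genes higher (18.3 expected, adjusted p = 4.52e-23) and mitochondrial inner membrane 100 of 361 (43.2 expected, adjusted p = 7.84e-14). For sesamin against control, kinetochore held 48 of 108 genes lower (23.9 expected, adjusted p = 0.000421) and rhythmic process 29 of 54 (12 expected, adjusted p = 0.000421). Fisher's test treats genes as independent replicates, which they are not, so these p-values may be far too small. For sesamin against oleic acid, 11 of 34 gene lists passed camera with the preset correlation and 0 with an estimated one. The calls behind these terms were made before trends on GC content and length were removed. Log2 fold change had a Spearman correlation with GC content of 0.443 for sesamin against oleic acid and 0.495 against control. Against control the mitotic list had a median of -0.32, or -0.14 with trends removed (camera adjusted p = 0.0848). In all, 32 terms passed with oleic acid, 118 for sesamin against oleic acid (47 without oleic acid replicate 1, 75 without oleic acid replicate 3) and 113 against control (72 without control replicate 3).

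Hypoxia and glycolysis genes, with a median log2 fold change of -0.997 with oleic acid, keep several explanations open. A trend on GC content or length as the whole cause is argued against by the median of -1.03 once both trends were removed (-1.06 to -1.02 over left-out libraries). PLIN2, which is known to rise with fatty acid, was lower in the libraries labelled oleic acid. An exchange of the control and oleic acid labels was therefore tested on PPAR targets. Their median of 0.20 (0.17 to 0.27 over left-out libraries, 10 higher and 6 lower) leaves it open. That list holds PLIN2 itself, with HILPDA and ANGPTL4, which fell, and CPT1A, ACSL1, CREB3L3, CIDEC and PDK4, which rose. The test was thus not independent of the fall of PLIN2 that raised the question. Whether PLIN2, HILPDA and ANGPTL4 fell as part of the hypoxia pattern itself was not tested either. Culture conditions such as density, medium or hours cannot be told apart from oleic acid, since the labels do not give them per group, and the mitotic median of 0.028 decides nothing. An effect of oleic acid itself may also account for the pattern and was not tested apart from these.

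Ribosomal protein and respiratory chain genes were higher with sesamin while fold changes followed GC content and length. With both trends removed, the ribosomal protein median was 0.20 (0.17 to 0.25 over left-out libraries, 0.28 before). The respiratory chain median was 0.23 (0.19 to 0.29, 0.25 before). These values argue against the trends, as measured here, as the whole cause of either. Part of each shift may still come from such trends, since both medians came closer to 0. GC content was that of the longest transcript, and length that of the deposited tables (list medians of 3591 and 2711 bases). The mRNAs expressed may be shorter, so a trend on their own length may remain and was not tested. The calls of both lists were lost with an estimated correlation, and reads shared with ribosomal pseudogenes were not tested. An effect of sesamin, or of hours in culture, also stays open.

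Cholesterol synthesis genes fell with oleic acid and were higher again with sesamin. Noise in the shared oleic acid libraries would give this shape, but 0 of 100 simulated sesamin groups with no effect reached the observed median of 0.27 (highest 0.10, SD 0.04). With trends on GC content and length removed the median was 0.38 (0.29 to 0.39 over left-out libraries), which argues against those trends as the whole cause. The sesamin call of the list was lost with an estimated correlation (camera, adjusted p = 0.0793). An effect of sesamin or of hours in culture, whose total the labels do not give per group, stays open and was not tested.

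The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, so the share of splits with as many genes called cannot be below 0.1. Only the real split, 1 of the 10 in each comparison, reached its own count of 2494, 3129 or 5815 genes. The highest of the other splits called 0 genes by edgeR in each comparison, with 491, 2066 and 1654 genes at an unadjusted p under 0.05 and 2, 12 and 1 by DESeq2. Every other split mixes libraries of both groups, so group differences enter the spread within its parts and few calls follow by construction.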
